A study of Mus musculus with 30 samples.

How the data were processed

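The series holds RNA-seq of mouse 4T1 tumours, with 3 populations (sorted 4T1 cells, CD4+ T cells and CD8+ T cells) under 2 treatments (control IgG1, called CTRL, and C269) and 5 samples in each of the 6 groups. Per the labels, all samples come from tumours, RNA was extracted with a Lexogen SPLIT kit and libraries were sequenced on a NextSeq 500. Per the submitters' processing notes, read quality was checked with FastQC, reads were counted with featureCounts and groups were compared with DESeq2, with mm9 named as the genome build. Versions and the aligner are not given in the sources used here.

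Of the 3 deposited tables, each holds 1 population, with 55408 rows and 10 library columns. The library columns and the condition columns hold counts as deposited by the authors, without normalization. The baseMean column is a signal, the mean of counts divided by the size factors that the authors computed with DESeq2. The fold change column is on the log2 scale, per the file headers, and gives CTRL over C269, the opposite direction to the one used here. The Wald statistic is a score from the authors' DESeq2 run, and the deposited p-value columns hold its p-value and the adjusted p-value. Only the counts were used for the tests here, and the authors' adjusted values were used for the counts of genes given beside them. Gene starts in the deposited tables were compared with GENCODE M21 (GRCm38): of 55401 gene identifiers 55141 were found and 54928 had the same start (99.6%), so coordinates are those of GRCm38 although the notes name mm9.

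The library columns carry numbers and no sample titles. Each condition column equals the sum of exactly 1 set of 5 library columns in 100% of genes with counts, out of 252 sets tried, and the next best set matched 28.3% to 31.1% of them. The condition number matches the number in the sample titles, which gives libraries 1 to 5 as 4T1 CTRL, 6 to 10 as 4T1 C269, 11 to 15 as CD4 CTRL, 16 to 20 as CD4 C269, 21 to 25 as CD8 CTRL and 26 to 30 as CD8 C269. The letters that tell replicates apart in the titles could not be assigned to columns. In the 4T1 table, 5 gene names had been turned into dates and were taken from another table by identifier.

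Ribosomal RNA made up 7 of the counted features, 28S holding 99.9978% of their counts. They were left out of library sizes and tests and held 3.05% of all counts, from 0.579% to 7.95% per library. The remaining 55401 genes were used. Total counts ran from 2178682 to 5208420 per library, and 12208 to 18972 genes had at least 1 count. Within groups the most similar replicates by a chi-square per gene were libraries 1 and 3 (5.19, where counting error alone gives about 1). The next closest 4T1 CTRL pair was at 24.9. In 4T1 C269, libraries 9 and 10 were at 11.1 and the next pair at 25.4. No pair was close enough to be the same library sequenced again, so n = 5 was kept. This check does not exclude that 2 libraries came from the same tumour, so n counts libraries.

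C269 was compared with CTRL within each population by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Differences of the C269 effect between populations were contrasts in an edgeR fit of all 30 libraries. In all, 34 gene lists (660 symbols, 654 found) were written before the data were examined and tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and at least 5 tested members. Camera with a correlation estimated per list and fry were run beside it. Marker levels in CTRL groups were compared by a two-sided exact permutation test of the mean log2 value over 252 assignments. CPM scale each count by the library's total of counts assigned to genes.

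Single genes were named by a fixed rule. It takes up to 8 passing genes per direction with at least 5 CPM in the higher group and, where none passes, the 5 with the smallest p per direction. It takes up to 4 passing members of each gene list, or the 2 members with the smallest p. It always includes Nampt, Cd274, Pdcd1, Ifng and 6 identity markers, and for the differences between populations the 6 genes with the smallest p. Some results under this rule are not reported here. Genes with a group at 0 in all its libraries were left out of the text where only a fold change would be given.

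The tests were tested on simulated data in which 200 genes were changed. Of genes changed 2-fold, 4-fold and 8-fold, edgeR recovered 2.99%, 56.7% and 75.8% in 4T1, 47.8%, 91% and 98.5% in CD4 and 28.4%, 73.1% and 80.3% in CD8, with 5, 12 and 3 false calls. DESeq2 recovered 13.4%, 70.1% and 90.9% in 4T1, 65.7%, 95.5% and 98.5% in CD4 and 34.3%, 82.1% and 89.4% in CD8, with 52, 30 and 31 false calls. For the differences between populations edgeR recovered 2.99%, 44.8% and 69.7% between CD4 and CD8, 4.48%, 46.3% and 74.2% between 4T1 and CD4 and 5.97%, 31.3% and 65.2% between 4T1 and CD8. A simulated list had all 31 members changed 2-fold and was drawn without correlation between genes. It was recovered in each population by camera with either correlation and by fry. Genes of the real lists can be correlated, so this does not show how the tests compare there.

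The alternatives set together with the gene lists were DESeq2 1.42.0, size factors of DESeq2 (RLE) or library size alone in the edgeR fit, no filter, a filter of at least 5 CPM in at least 5 libraries, a single fit of all 30 libraries, a 2-fold threshold, and leaving out each library in turn. Alternatives chosen after seeing the data were the 4T1 libraries without libraries 9 and 10, the CD8 libraries without libraries 27 and 29, and fits that kept the ribosomal RNA. Organ and mammary marker lists used only in the closing section were also written after the data were seen.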

Results

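RNA was sequenced from 30 mouse tumour libraries in 6 groups of 5. The tumours were of 4T1, a mouse mammary carcinoma line that here carried green fluorescent protein. Mice received a control IgG1 (CTRL) or C269, an antibody against the extracellular form of nicotinamide phosphoribosyltransferase (NAMPT), at 2.5 mg/kg 2 times a week for 1 month. NAMPT makes the NAD precursor nicotinamide mononucleotide inside cells, and outside cells it acts as a cytokine. From the tumours, sorted 4T1 cells, CD4+ T cells and CD8+ T cells taken with magnetic beads were each profiled in 5 CTRL and 5 C269 samples. The series title puts the question as whether neutralising extracellular NAMPT alters T cell responses and the axis of PD-1, an inhibitory receptor of T cells, and its ligand PD-L1.

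Total counts per library ran from 2490921 to 5208420 in the 4T1 groups, from 3556439 to 4575387 in the CD4 groups and from 2178682 to 4036860 in the CD8 groups. The 5 CD8 C269 libraries were the shallowest group, with 2178682 to 3352029 counts and 12208 to 15786 genes detected, against 15775 to 17169 genes in CD8 CTRL. Levels are given in CPM, with only counts assigned to genes in the library total, as mean ± SD with n = 5 per group unless another n is given, and fold changes are C269 minus CTRL on the log2 scale with their standard error (SE). The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. Libraries are called by the number that heads their column in the deposited tables.

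The T cell markers followed the labels. Cd4, the co-receptor of helper T cells, averaged 160.4 ± 50.3 CPM in CD4 CTRL, 6.495 ± 4.36 CPM in CD8 CTRL and 0.749 ± 1.11 CPM in 4T1 CTRL. Cd8a, the co-receptor of cytotoxic T cells, averaged 462 ± 102 CPM in CD8 CTRL against 14.97 ± 5.08 CPM in CD4 CTRL and 1.72 ± 2.43 CPM in 4T1 CTRL. Cd3e, a subunit of the T cell receptor complex, averaged 12.97 ± 8.31, 177 ± 38.0 and 409 ± 39.9 CPM in 4T1, CD4 and CD8 CTRL. Each of these 3 markers differed between CD4 CTRL and both other control groups (two-sided exact permutation test, p = 0.00794, the smallest that 5 against 5 allows; Benjamini-Hochberg adjusted 0.0119 over 12 tests).

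The epithelial markers did not separate the tumour fraction from the CD4 fraction. Krt8, a keratin of simple epithelia, averaged 89.7 ± 52.9 CPM in 4T1 CTRL and 86.6 ± 11.6 CPM in CD4 CTRL, a difference of -0.09 on the log2 scale (exact permutation p = 0.794). Epcam, an epithelial adhesion molecule, averaged 22.7 ± 13.99 and 15.3 ± 7.99 CPM in these groups (difference 0.50, exact permutation p = 0.357). Both were lower in CD8 CTRL than in CD4 CTRL, by -2.54 for Krt8 (exact permutation p = 0.00794) and -1.48 for Epcam (exact permutation p = 0.0159). Ptprc, the pan-leukocyte surface protein CD45, averaged 522 ± 199 CPM in 4T1 CTRL and 1074 ± 263 CPM in CD4 CTRL. S100a8, an abundant neutrophil transcript, averaged 4167 ± 1965 CPM in 4T1 CTRL against 286 ± 44.1 CPM in CD4 CTRL and 176 ± 43.2 CPM in CD8 CTRL.

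**Figure D1:**
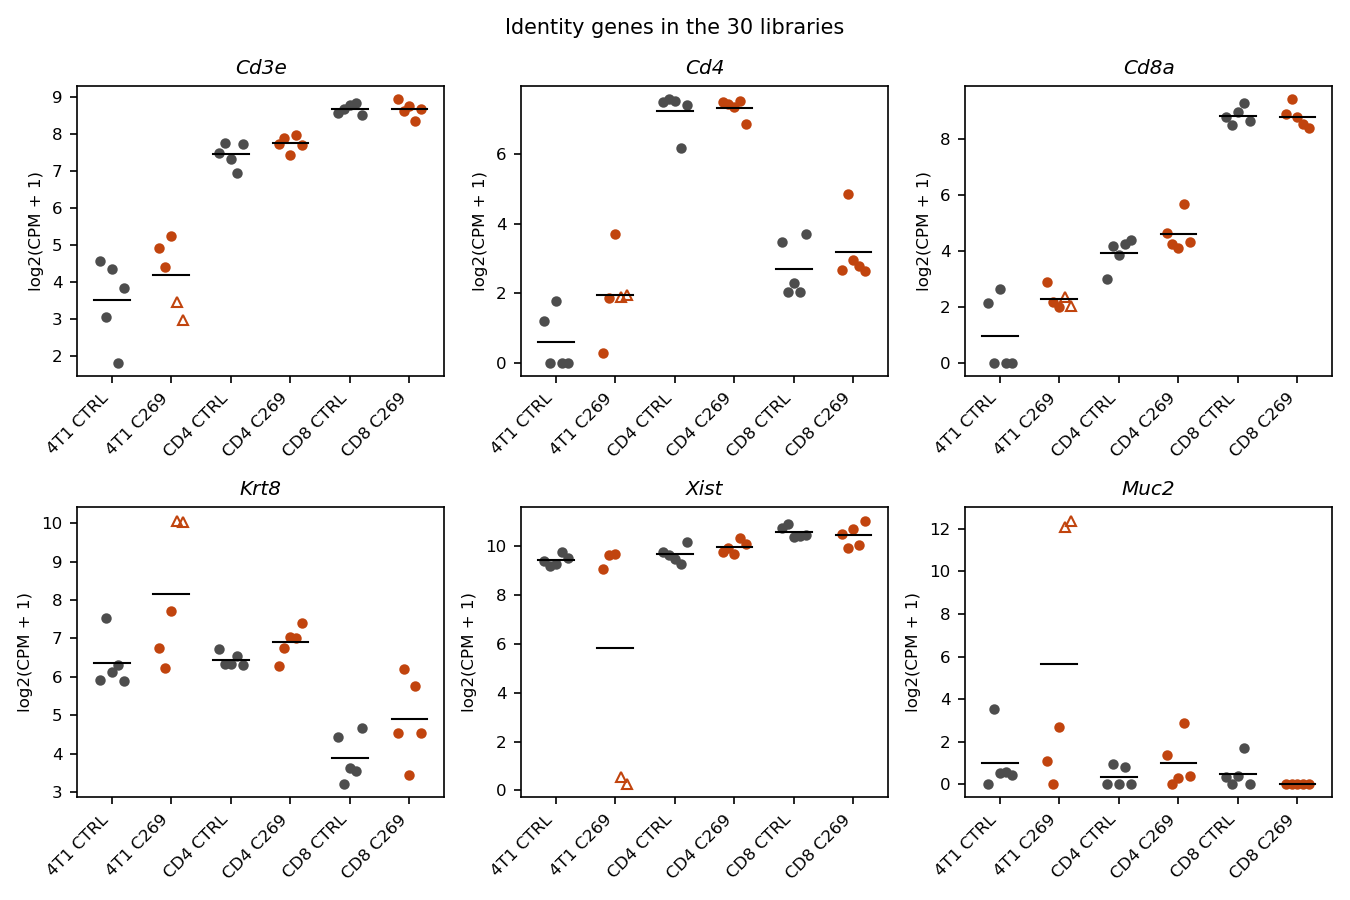
Each panel plots log2(CPM + 1) of a gene in each of the 30 libraries, by group, with CTRL in grey, C269 in orange and a horizontal line at the group mean. Open triangles are libraries 9 and 10, labelled 4T1 C269, in which Muc2 was at 4408 and 5348 CPM and Xist at 0.449 and 0.193 CPM.

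The first comparison asked what C269 did to the tumour fraction. In the 4T1 libraries, genes of epithelial cells and of mitochondrial respiration had higher values in C269, and genes of inflammation, hypoxia, macrophages and fibroblasts had lower ones, while 0 of 12875 single genes passed the test over all genes. Each of these list calls was lost with an estimated correlation (adjusted p between 0.724 and 0.836), and those of mitochondrial respiration and fibroblasts were lost without libraries 9 and 10 (camera adjusted p = 0.0667 and 0.201). Fgfr2, a receptor for fibroblast growth factors, averaged 2.14 ± 1.51 CPM in CTRL and 41.5 ± 32.2 CPM in C269 (log2 fold change 4.21, SE 0.65; 4.26, SE 0.72, without libraries 9 and 10). Scnn1a, a subunit of the epithelial sodium channel, averaged 0.233 ± 0.238 and 14.98 ± 12.1 CPM (5.68, SE 0.89; 4.55, SE 1.01, without these libraries). Csn1s2a, a milk casein, averaged 12.2 ± 4.76 CPM in CTRL and 0.504 ± 0.532 CPM in C269 (-4.50, SE 0.90; -3.75, SE 0.70, without them).

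Libraries 9 and 10, both labelled 4T1 C269, stood apart from the other 28 libraries. Muc2, the secreted mucin of intestinal goblet cells, was at 4408 and 5348 CPM in them and at no more than 10.6 CPM in any other library. Xist, the transcript that silences an X chromosome in female cells, was at 0.449 CPM (2 counts) and 0.193 CPM (1 count), against at least 528 CPM in each of the other 28. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y summed to 208 and 210.4 CPM in libraries 9 and 10 and to at most 1.39 CPM elsewhere. For this reason the 4T1 fold changes are given with all 10 libraries and also without these, a choice made after seeing the data.

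Of the epithelial and luminal list, 13 members were tested in 4T1, 11 were higher in C269 and 2 lower. None passed over all genes and 11 passed when adjusted over the list alone. Krt19, a luminal keratin, averaged 25.04 ± 16.1 CPM in CTRL and 863 ± 943 CPM in C269 (log2 fold change 5.08, SE 1.00), and without libraries 9 and 10 its fold change was 2.92 (SE 0.60). Krt7, another simple-epithelial keratin, had a fold change of 2.69 (SE 0.51), or 1.97 (SE 0.46) without those libraries. The list rose as a group (camera with a preset correlation, adjusted p = 6.77e-06; adjusted p = 0.724 with an estimated correlation). Without libraries 9 and 10 it also rose, with 12 of 13 members higher and 6 passing when adjusted over the list alone (camera adjusted p = 9e-06; adjusted p = 0.531 with an estimated correlation). Genes with the smallest p in the 8 remaining libraries included Cited1, a transcriptional co-regulator of hormone-responsive mammary cells (3.40, SE 0.48), Ptn, the growth factor pleiotrophin (4.19, SE 0.67), and Prlr, the prolactin receptor (3.77, SE 0.73), none of which passed over all genes (edgeR quasi-likelihood test, smallest adjusted p = 0.360). Library 8 was highest for each: Cited1 was at 47.2, 35.9 and 215 CPM in libraries 6, 7 and 8 (9.27 ± 1.58 in CTRL), Ptn at 58.7, 88.5 and 704.7 CPM (14.97 ± 6.32 in CTRL) and Prlr at 130.5, 85.5 and 682 CPM (22.4 ± 16.3 in CTRL).

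Genes of inflammation and of the myeloid compartment fell as lists in 4T1. Of 27 NF-kB and inflammatory cytokine genes, 25 were lower in C269, among them Vcam1, an endothelial and stromal adhesion molecule (157.5 ± 67.4 to 57.0 ± 22.6 CPM; -1.37, SE 0.36, and -0.97, SE 0.30, without libraries 9 and 10), and the neutrophil chemoattractant Cxcl5 (-1.29, SE 0.41, and -1.09, SE 0.47). This list fell by camera (adjusted p = 4.55e-09; adjusted p = 0.756 with an estimated correlation). The macrophage and monocyte list fell with 15 of 17 members lower, 3 of them passing when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.8e-07; adjusted p = 0.756 with an estimated correlation). Its members C1qa and C1qb, subunits of the complement component C1q, had fold changes of -2.43 (SE 0.64) and -2.12 (SE 0.57), or -2.25 (SE 0.78) and -1.77 (SE 0.64) without libraries 9 and 10. The CTRL libraries differed widely in them: C1qa averaged 417 ± 467 CPM in CTRL and 70.35 ± 24.35 CPM in C269, and C1qb 218 ± 208 and 45.7 ± 19.7 CPM. Both lists fell again without libraries 9 and 10, with camera adjusted p of 0.00125 and 0.00832 (adjusted p = 0.619 for each with an estimated correlation).

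Hypoxia and glycolysis genes fell as lists, and in each 2 members were higher in C269. Ndrg1, a stress-response gene induced by low oxygen, averaged 600.4 ± 208 CPM in CTRL and 260.5 ± 102 CPM in C269 (-1.12, SE 0.34, and -0.75, SE 0.28, without libraries 9 and 10). P4ha1, a collagen prolyl hydroxylase subunit, had a fold change of -1.61 (SE 0.49), or -1.10 (SE 0.38) without them, and Hk2, the hexokinase that starts glycolysis, one of -0.78 (SE 0.30), or -0.95 (SE 0.33). Camera gave adjusted p = 0.000131 for hypoxia (adjusted p = 0.724 with an estimated correlation) and 0.000165 for glycolysis (adjusted p = 0.756 with an estimated correlation). Both lists fell without libraries 9 and 10 as well, with camera adjusted p of 0.00127 and 0.0450 (adjusted p = 0.531 and 0.619 with an estimated correlation). The mesenchymal and invasion list also fell, with 20 of 22 members lower and Mmp13, a collagenase, at -2.84 (SE 0.74, and -2.32, SE 0.77, without libraries 9 and 10; camera adjusted p = 7.07e-06; adjusted p = 0.756 with an estimated correlation). It fell too without libraries 9 and 10 (camera adjusted p = 0.00964, or 0.619 with an estimated correlation). Mmp13 also varied widely in CTRL, at 301 ± 266 CPM against 37.0 ± 27.6 CPM in C269.

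Several 4T1 list calls held only with libraries 9 and 10 in the fit. Oxidative phosphorylation rose with 28 of 29 members higher (camera adjusted p = 4.15e-06; adjusted p = 0.756 with an estimated correlation), and its adjusted p was 0.0667 without them. The interferon-gamma and JAK-STAT list fell with 24 of 32 members lower (camera adjusted p = 0.00657; adjusted p = 0.878 with an estimated correlation), and its adjusted p was 0.782 without them and 0.0631 without library 10 alone. Ifngr1, a chain of the interferon-gamma receptor and the list's member with the smallest p, went the other way, at 113 ± 34.9 CPM in CTRL and 232 ± 65.3 CPM in C269 (1.02, SE 0.30, and 1.02, SE 0.34, without libraries 9 and 10). Type I interferon, immediate early, neutrophil and fibroblast genes fell as lists in the full set (camera adjusted p = 0.00152, 1.26e-05, 1.05e-05 and 0.00152; adjusted p = 0.756, 0.765, 0.756 and 0.836 with an estimated correlation), and their adjusted p was 0.101, 0.386, 0.206 and 0.201 without them. The fibroblast call was also lost without CTRL library 5 (camera adjusted p = 0.125). Mx2, an interferon-induced GTPase, had a fold change of -1.66 (SE 0.46) with all libraries and -1.24 (SE 0.45) without these. Klf6, an early response transcription factor, had -0.96 (SE 0.40) and -0.49 (SE 0.23), Mmp8, a neutrophil collagenase, -1.58 (SE 0.73) and -0.90 (SE 0.34), Ly6g, a neutrophil surface protein, 2.74 (SE 0.93) and 0.07 (SE 0.55), and Pdgfra, a PDGF receptor of fibroblasts, -0.75 (SE 0.33) and -0.53 (SE 0.36).

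T cell genes were measured at low levels in the 4T1 fraction, and the CTRL libraries differed among themselves. Libraries 1 and 3 held Cd3e at 22.7 and 19.3 CPM, the B cell gene Ms4a1 at 155.7 and 159 CPM and the red cell globin Hbb-bs at 11510 and 12080 CPM, within or near the range of C269 libraries 6 to 8 (Cd3e 20.1 to 36.7, Ms4a1 68.2 to 319.9 and Hbb-bs 4741 to 18140 CPM). Libraries 2, 4 and 5 held Cd3e at 2.51 to 13.2 CPM, Ms4a1 at 0 to 5.96 CPM and Hbb-bs at 94.3 to 744.5 CPM. Of 18 T cell markers, 17 were higher with all libraries and 18 without libraries 9 and 10, and the list rose in each set (camera adjusted p = 0.000685 and 9.45e-09; adjusted p = 0.831 and 0.531 with an estimated correlation). Bcl11b, a T lineage transcription factor, averaged 6.81 ± 8.09 CPM in CTRL and 45.6 ± 27.01 CPM in C269 (2.62, SE 0.95, and 1.89, SE 1.01, without libraries 9 and 10). Without libraries 9 and 10, lists of cytotoxic effectors, T cell dysfunction, T cell activation, Th1 and Th2 with Th17 genes, NK cell and B cell markers, immune checkpoints and ribosomal proteins rose by camera (adjusted p between 0.000469 and 0.0471; adjusted p between 0.531 and 0.639 with an estimated correlation). The ribosomal protein list had 18 of 35 members lower with all libraries and 35 of 35 higher without libraries 9 and 10.

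The genes that bear on the study's question had no change past the threshold in 4T1. Nampt averaged 164 ± 88.6 CPM in CTRL and 114 ± 31.2 CPM in C269 (-0.45, SE 0.34, and -0.19, SE 0.35, without libraries 9 and 10). Cd274, which encodes PD-L1, averaged 309 ± 76.0 and 211 ± 207 CPM (-0.42, SE 0.84), and its fold change was 0.28 (SE 0.36) without libraries 9 and 10, in which it was at 19.8 and 11.01 CPM. Ifng, the gene of interferon-gamma, had a fold change of 0.33 (SE 1.5), or 1.03 (SE 1.41) without those libraries. The NAD metabolism list had 14 of 25 members higher (camera adjusted p = 0.835), and the immune checkpoint list 6 of 12 (camera adjusted p = 0.601). Without libraries 9 and 10 the checkpoint list rose by camera with the preset correlation, and this call was lost with an estimated correlation.

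By edgeR's quasi-likelihood test 0 of 12875 genes passed in 4T1 and 1557 had an unadjusted p under 0.05, while DESeq2 called 1002 genes, 559 higher and 443 lower in C269. Without libraries 9 and 10, edgeR called 0 of 13750 genes (751 with an unadjusted p under 0.05) and DESeq2 99, of which 26 were higher. The authors' deposited table lists 818 genes with an adjusted p under 0.05, 418 higher in C269 and 400 higher in CTRL. Counts were also simulated for this comparison from all libraries, 9 and 10 included. In them the edgeR test recovered 2.99% of genes changed 2-fold, 56.7% of those changed 4-fold and 75.8% of those changed 8-fold. It made 5 false calls there, and DESeq2 made 52.

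**Figure D2:**
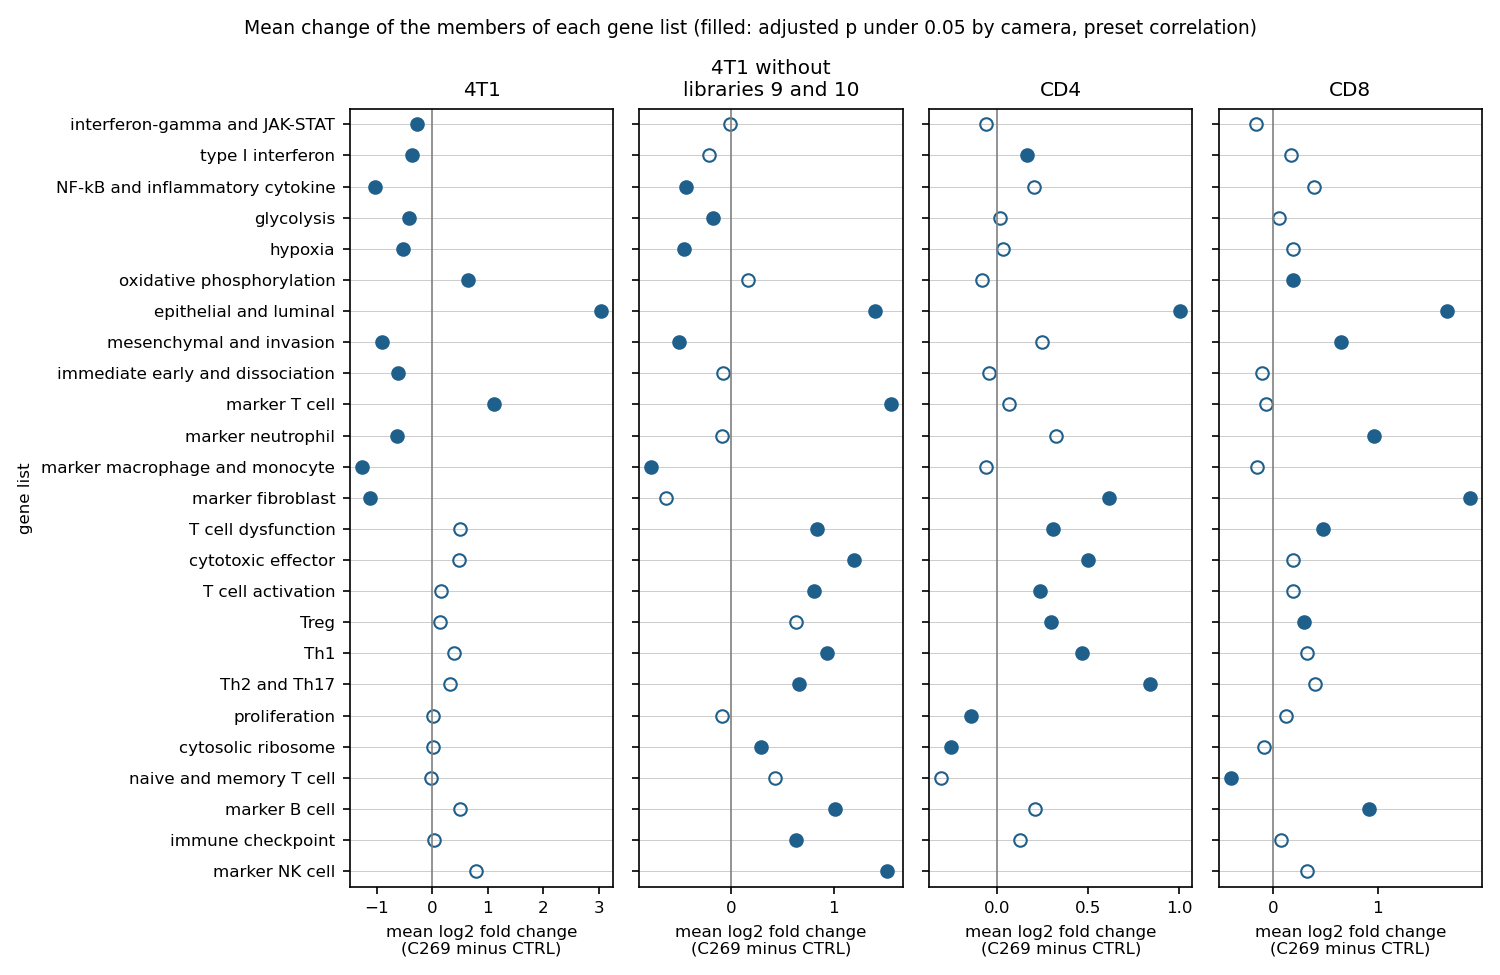
For each fixed gene list that passed in at least 1 set, the point is the mean log2 fold change of its tested members, C269 minus CTRL, in 4T1 with all 10 libraries, in 4T1 without libraries 9 and 10, in CD4 and in CD8. Filled points passed camera with the preset correlation, and 0 lists passed with an estimated correlation; the epithelial and luminal mean was 3.04, 1.40, 1.01 and 1.66 in these sets.

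The second comparison asked what C269 did to CD4+ T cells of the tumour. In C269 the lists of Th2 and Th17, Th1, cytotoxic, regulatory, activation and dysfunction genes rose as groups and ribosomal protein and cell cycle genes fell as groups, while 0 of 12393 single genes passed the test over all genes. Each of these list calls was lost with an estimated correlation (adjusted p between 0.205 and 0.804). Gata3, the transcription factor that directs Th2 cells and is also used by tissue regulatory T cells, averaged 181.5 ± 30.7 CPM in CTRL and 318 ± 72.0 CPM in C269 (log2 fold change 0.79, SE 0.16), with 4 of 5 C269 libraries above every CTRL library. Il1rl1, which encodes the interleukin-33 receptor ST2, averaged 99.1 ± 43.9 and 257 ± 98.7 CPM (1.35, SE 0.30), again with 4 of 5 above every CTRL library. Cxcr6, a chemokine receptor of tissue-resident and effector T cells, averaged 43.1 ± 13.6 and 99.0 ± 26.7 CPM (1.18, SE 0.21).

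Of the Th2 and Th17 list, 13 of 14 tested members were higher in CD4 C269, 0 passed over all genes and 7 passed when adjusted over the list alone. The list rose by camera (adjusted p = 1.82e-08; adjusted p = 0.205 with an estimated correlation). The regulatory T cell list rose with 14 of 15 members higher and 4 passing when adjusted over the list alone (camera adjusted p = 0.000114; adjusted p = 0.332 with an estimated correlation). Its members Il2ra, the high-affinity chain of the interleukin-2 receptor, and Ikzf2, the transcription factor Helios, had fold changes of 0.92 (SE 0.22) and 0.51 (SE 0.18). Th1 genes rose as a list with 13 of 14 members higher and 1 passing when adjusted over the list alone (camera adjusted p = 5.34e-05; adjusted p = 0.205 with an estimated correlation). Il18rap, an interleukin-18 receptor chain, was among them at 0.80 (SE 0.27).

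Cytotoxic effector genes rose as a list in CD4, with 19 of 22 members higher and 0 passing when adjusted over the list alone (camera adjusted p = 2.24e-06; adjusted p = 0.205 with an estimated correlation). Gzmb, the protease granzyme B, averaged 43.9 ± 13.02 CPM in CTRL and 92.0 ± 63.2 CPM in C269 (1.03, SE 0.33), and Klrd1, the NK receptor CD94, had a fold change of 0.90 (SE 0.32). Cd8a, a marker of other T cells, had higher values in the same libraries, at 14.97 ± 5.08 CPM in CTRL and 25.6 ± 14.3 CPM in C269, and library 19 was highest for both Cd8a (50.62 CPM) and Klrd1 (45.13 CPM). T cell activation genes rose with 14 of 19 members higher, 1 passing when adjusted over the list alone, and T cell dysfunction genes with 14 of 16 (camera adjusted p = 0.00142 and 0.00203; adjusted p = 0.596 and 0.332 with an estimated correlation). Tnfrsf18, the co-stimulatory receptor GITR, had a fold change of 0.53 (SE 0.19). Type I interferon genes rose by a mean of 0.16 with 22 of 25 members higher (camera adjusted p = 0.0335; adjusted p = 0.804 with an estimated correlation), among them the RNA sensor Ifih1 at 0.31 (SE 0.14). This call was lost without any 1 of libraries 12, 15, 19 or 20 (camera adjusted p between 0.180 and 0.330), and that of T cell activation without library 14 (0.240).

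The ribosomal protein list fell in CD4, with 33 of 35 members lower and a mean of -0.25 (camera adjusted p = 2.6e-07; adjusted p = 0.804 with an estimated correlation). Rpl3, a large-subunit protein, averaged 824 ± 151 CPM in CTRL and 600.1 ± 112 CPM in C269 (-0.48, SE 0.18). The proliferation list fell with 26 of 31 members lower (camera adjusted p = 0.00572; adjusted p = 0.804 with an estimated correlation), with Mcm5, a subunit of the replicative helicase, at -0.48 (SE 0.23), and this call was lost without library 19 (camera adjusted p = 0.0831). Tuba1b, an alpha-tubulin, was among the genes with the smallest p for a lower value, at 735 ± 120.5 CPM in CTRL and 473 ± 102 CPM in C269 (-0.65, SE 0.18). None of these lists' members passed when adjusted over the list alone.

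Markers of other cells moved with C269 in the CD4 libraries too. The epithelial and luminal list rose with 12 of 13 members higher and 5 passing when adjusted over the list alone (camera adjusted p = 6.41e-08; adjusted p = 0.205 with an estimated correlation). Krt19 averaged 19.2 ± 10.9 CPM in CTRL and 94.7 ± 76.3 CPM in C269 (2.26, SE 0.55), and Cdh1, the epithelial cadherin, 13.7 ± 3.59 and 35.4 ± 21.7 CPM (1.33, SE 0.34). Cited1 averaged 3.93 ± 2.78 and 29.4 ± 19.7 CPM (2.86, SE 0.54), and Slc12a2, a sodium, potassium and chloride co-transporter of secretory epithelia, 37.8 ± 8.77 and 89.9 ± 39.5 CPM (1.22, SE 0.26). Fibroblast markers rose as a list with 13 of 13 members higher and 0 passing when adjusted over the list alone (camera adjusted p = 0.00572; adjusted p = 0.804 with an estimated correlation), with Lum, a matrix proteoglycan, at 1.00 (SE 0.54). The fibroblast call was lost without library 20, where Lum was at 88.01 CPM against at most 17.2 CPM in the other C269 libraries (camera adjusted p = 0.448), and without library 14 (0.0749).

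Pdcd1, which encodes PD-1, averaged 31.9 ± 15.4 CPM in CD4 CTRL and 67.3 ± 38.9 CPM in CD4 C269, a fold change of 1.04 (SE 0.35) that did not pass over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.760). Cd274 had a fold change of -0.08 (SE 0.18), Nampt -0.11 (SE 0.14) and Ifng 0.43 (SE 0.38). The immune checkpoint list had 7 of 13 members higher (camera adjusted p = 0.917), and NAD metabolism 11 of 22 (camera adjusted p = 0.611).

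In CD4, edgeR called 0 of 12393 genes and 697 had an unadjusted p under 0.05, while DESeq2 called 16 genes, all of them higher in C269. These included Cited1 (DESeq2 adjusted p = 0.000174), Cxcr6 (0.00246), Il1rl1 (0.0115) and Gata3 (0.0131). Beside them stood Aqp5, a water channel of secretory glands, which is named here after its value was seen (DESeq2 log2 fold change 3.45, SE 0.82). The authors' deposited table lists 12 genes with an adjusted p under 0.05, all higher in C269. Without CTRL library 15 edgeR called 10 genes, and Cxcr6 (adjusted p = 0.0150) and Il1rl1 (adjusted p = 0.0426) were among them. On simulated counts of this comparison edgeR recovered 47.8% of genes changed 2-fold and 91% of those changed 4-fold. It made 12 false calls there, and DESeq2 made 30.

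The third comparison asked the same of CD8+ T cells. Cd24a (ENSMUSG00000047139; chromosome 10, start 43578284 in the deposited tables), a small surface glycoprotein of B cells, epithelia and immature lymphocytes, rose from 21.8 ± 7.14 CPM in CTRL to 95.3 ± 36.0 CPM in C269 (log2 fold change 2.13, SE 0.30) and was the only gene of 10943 to pass. Each of the 5 C269 libraries lay above every CTRL library, the lowest at 53.9 CPM and the highest CTRL library at 32.9 CPM. Naive and memory T cell genes fell as a list, and lists of T cell dysfunction, regulatory T cell and respiratory chain genes rose, as did lists of fibroblast, epithelial, neutrophil and B cell markers. Each of these calls was lost with an estimated correlation (adjusted p = 0.536) and without libraries 27 and 29 (camera adjusted p between 0.0736 and 0.478).

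The call of Cd24a (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0289) stood without library 25 or 26 and was lost without any 1 of the other 8 libraries, with adjusted p between 0.0540 and 0.199. Libraries 27 and 29 had the highest Krt8 levels of CD8 C269, and also the lowest total counts, the fewest genes detected (12208 and 13400) and the highest ribosomal RNA share (7.95% and 7.24%) of all 30 libraries. Without them the fold change of Cd24a was 1.74 (SE 0.27, edgeR adjusted p = 0.0917), and 0 of 11867 genes passed (576 with an unadjusted p under 0.05). This subset was chosen after seeing the data.

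Of the naive and memory list, 16 of 17 members were lower in CD8 C269 and 0 passed when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.536 with an estimated correlation). Dapl1, a gene of naive and long-lived CD8 cells, averaged 226 ± 50.9 CPM in CTRL and 109.9 ± 72.7 CPM in C269 (-1.03, SE 0.37), and Bcl2, the survival factor, 452 ± 60.6 and 322 ± 86.6 CPM (-0.48, SE 0.18). T cell dysfunction genes rose with 15 of 17 members higher and 1 passing when adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 0.536 with an estimated correlation), with Tox2, a transcription factor of exhausted and follicular helper T cells, at 3.41 (SE 0.88). Tox2 also had a higher value in 4T1 C269 without libraries 9 and 10, at 1.18 and 27.01 CPM (4.28, SE 1.01), beside the epithelial genes. Regulatory T cell genes rose with 8 of 12 members higher (camera adjusted p = 0.0454; adjusted p = 0.536 with an estimated correlation), with Tnfrsf18 at 0.68 (SE 0.30). Oxidative phosphorylation genes rose by a mean of 0.19 with 24 of 29 higher (camera adjusted p = 0.00119; adjusted p = 0.536 with an estimated correlation). Without libraries 27 and 29 the camera adjusted p of these lists was 0.195, 0.344, 0.140 and 0.287, in the order given. The regulatory T cell call was lost without any 1 of libraries 22, 23, 25, 26, 29 or 30 (camera adjusted p between 0.0561 and 0.268), and the dysfunction call without 22, 26 or 27 (0.0534 to 0.158).

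Marker lists of other cells also rose in CD8. Fibroblast markers had 11 of 11 members higher and 9 passing when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.536 with an estimated correlation), with Postn, a matricellular protein, at 11.2 ± 4.60 CPM in CTRL and 53.5 ± 59.5 CPM in C269 (2.27, SE 0.64). Epithelial genes had 7 of 7 members higher and 2 passing when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.536 with an estimated correlation), with Epcam at 4.39 ± 1.35 and 24.05 ± 25.8 CPM (2.42, SE 0.73). Neutrophil markers had 13 of 13 members higher, mesenchymal and invasion genes 15 of 19 and B cell markers 12 of 13, and these lists rose as well (camera adjusted p = 0.00459, 0.0158 and 0.00483; adjusted p = 0.536, 0.597 and 0.536 with an estimated correlation). Ms4a1, the B cell surface protein CD20, averaged 5.40 ± 3.89 and 35.4 ± 18.01 CPM (2.72, SE 0.54), and Ighm, the immunoglobulin mu chain, 143 ± 29.6 and 412 ± 252 CPM (1.55, SE 0.34). The immunoglobulin gamma chains Ighg2b and Ighg2c were among the genes with the smallest p for a lower value, at 42.2 ± 39.9 and 4.57 ± 5.16 CPM (-3.11, SE 0.82) and 34.9 ± 28.9 and 3.24 ± 3.47 CPM (-3.33, SE 0.94). In library 27 Epcam was at 64.3 CPM and Krt8 at 73.3 CPM, and in library 29 S100a8 was at 923 CPM and Col1a1, a fibrillar collagen chain, at 1065 CPM. Without libraries 27 and 29 the camera adjusted p of these 5 lists lay between 0.0736 and 0.478. Leaving out single libraries ended the B cell call without 28 (camera adjusted p = 0.102), the neutrophil and fibroblast calls without 29 (0.205 and 0.0692) and the mesenchymal call without 22, 26, 29 or 30 (0.0626 to 0.205).

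The interferon-gamma and JAK-STAT list had 23 of 31 members lower with a camera adjusted p of 0.0723, and without libraries 27 and 29 it fell (camera adjusted p = 0.0292; adjusted p = 0.923 with an estimated correlation), as did the macrophage and monocyte list (camera adjusted p = 0.0257; adjusted p = 0.923 with an estimated correlation). Pdcd1 averaged 139 ± 74.6 CPM in CTRL and 187 ± 121.5 CPM in C269 (0.43, SE 0.41), Cd274 122 ± 23.6 and 114 ± 37.1 CPM (-0.09, SE 0.24), Ifng 86.4 ± 30.9 and 103 ± 44.1 CPM (0.27, SE 0.32), and Nampt 90.1 ± 11.3 and 104 ± 28.5 CPM (0.21, SE 0.19). Prkcq, the protein kinase C theta of T cell receptor signalling, had the smallest p among lower values, at 72.1 ± 2.89 CPM in CTRL and 36.6 ± 11.3 CPM in C269 (-0.96, SE 0.23). The immune checkpoint list had 6 of 13 members higher (camera adjusted p = 0.541) and NAD metabolism 9 of 20 (camera adjusted p = 0.770).

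In CD8, 725 genes had an unadjusted p under 0.05 by edgeR, and DESeq2 called 15 genes, all higher in C269, among them Cd24a (DESeq2 adjusted p = 2.75e-07), Ms4a1 (0.00191), Prlr (0.00348), Ighm (0.0119), Ptn (0.0312) and Tox2 (0.0322), of which Prlr and Ptn are named after their values were seen. The authors' deposited table lists 13 genes with an adjusted p under 0.05, 12 higher in C269 and 1 higher in CTRL. On simulated counts of this comparison edgeR recovered 28.4% of genes changed 2-fold and 73.1% of those changed 4-fold. It made 3 false calls there, and DESeq2 made 31.

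**Figure D3:**
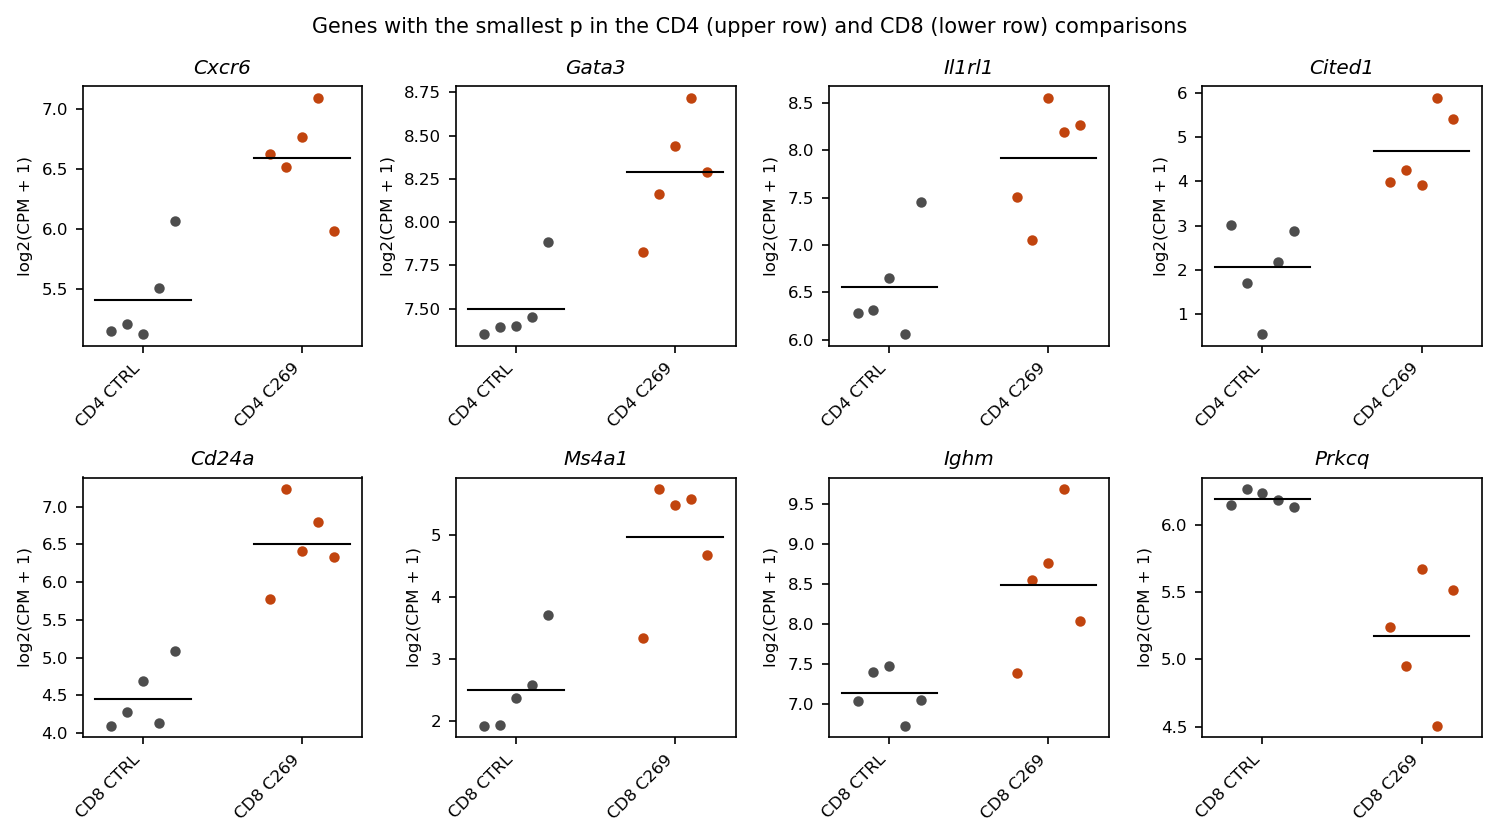
Each panel plots log2(CPM + 1) of a gene in the 5 CTRL (grey) and 5 C269 (orange) libraries, with a horizontal line at the group mean, for CD4 in the upper row and CD8 in the lower row. Cd24a is the gene that passed, with every C269 library above every CTRL library; the mean CPM was 21.8 and 95.3.

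The last comparisons tested whether the C269 effect differed between populations. Celsr1, an adhesion receptor of planar cell polarity, was the gene that passed between the tumour fraction and each T cell population. It averaged 0.132 CPM in 4T1 CTRL and 19.3 CPM in 4T1 C269, against 12.7 and 16.1 CPM in CD4 and 25.7 and 21 CPM in CD8. The difference of its C269 effect was 6.36 on the log2 scale (SE 1.09) between 4T1 and CD4 (edgeR interaction contrast, adjusted p = 0.0378) and 7.002 (SE 1.09) between 4T1 and CD8 (adjusted p = 0.00762). Without libraries 9 and 10 these were 4.31 (SE 0.91, adjusted p = 0.441) and 4.95 (SE 0.90, adjusted p = 0.0504), with 4.79 CPM in 4T1 C269.

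Between 4T1 and CD8, Hap1, a huntingtin-binding protein, had a difference of 5.63 (SE 1.05, edgeR adjusted p = 0.0608) and Hmgn5, a nucleosome-binding protein, of 1.95 (SE 0.38, adjusted p = 0.0608). Hap1 passed without libraries 9 and 10 at 6.10 (SE 1.05, edgeR adjusted p = 0.0427), with 4.30 and 16.3 CPM in 4T1 CTRL and the 3 remaining 4T1 C269 libraries and 2.02 and 0.0746 CPM in CD8 CTRL and C269. Between 4T1 and CD4, Atp1b1, a sodium pump subunit, had 5.07 (SE 1.04) and Mboat1, a lysophospholipid acyltransferase, 4.14 (SE 0.90), neither past the threshold (edgeR adjusted p = 0.206 for each). Between CD4 and CD8, 0 of 14731 genes passed the edgeR interaction contrast and 566 had an unadjusted p under 0.05, with Rrp15, a ribosome biogenesis factor, at -1.28 (SE 0.32) and Nipsnap1, a mitochondrial protein, at 1.20 (SE 0.33). DESeq2 was not run on these contrasts. The call of Celsr1 between 4T1 and CD4 was lost in the fit of the 20 libraries of these populations (edgeR adjusted p = 0.413), and so was that between 4T1 and CD8 (adjusted p = 0.180). The call between 4T1 and CD4 was also lost without any 1 of libraries 1, 2, 4, 5, 9, 10, 11, 13 or 15 to 20 (adjusted p between 0.0689 and 0.177).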

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

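Of the tests in this part, only the basal mammary test and the CD4 test without a single library were chosen before the result was seen, and the others only after it. Samples far from the rest of their group were looked for by Dixon's test in 250 sets of 5 values. Each set was a gene or a depth measure in 1 of the 6 groups. The test marked 23. Chance alone would mark about 1 in 20 sets, or 12.5, if the values were independent and normal. The sets reuse the same 30 libraries and the values were not on a log scale, so 12.5 is only a rough guide.

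In 4T1 CTRL, library 4 was high in Cxcl9 (382.5 CPM, nearest 94.5), library 2 in Oasl1 (437, nearest 184), Mmp8 (180.6, nearest 98.7) and Krt8 (183.1, nearest 78.8), and library 5 in Pdgfra (184.9, nearest 92.9) and Lum (509.8, nearest 129.5). In 4T1 C269, library 8 was high in Tlcd4 (129 CPM, nearest 30.7), Mroh2a (3.918, nearest 1.13) and Cd4 (12, nearest 2.90). In CD4 CTRL, library 15 was high in Fam25c (5.047 CPM, nearest 0), Gata3 (235.9, nearest 174) and Il2ra (179.7, nearest 106.6), while library 14 was high in Nampt (174.5, nearest 121.9) and low in Cd4 (71.27, nearest 172.1). In CD4 C269, library 19 was high in Fam25c (82.54 CPM, nearest 19.9), Klrd1 (45.13, nearest 20.02) and Cd8a (50.62, nearest 24.2), and library 20 in Lum (88.01, nearest 17.2). In CD8 CTRL, library 25 was high in Ms4a1 (12.16 CPM, nearest 5.00). In CD8 C269, library 29 was high in Mmp2 (158.1 CPM, nearest 47.4) and Lum (92.38, nearest 24.9), and library 27 in Nampt (154.1, nearest 102.6) and Cd4 (27.92, nearest 6.73). With libraries 9 and 10 in the fit, the difference of Celsr1 between C269 and CTRL was 6.36 larger in 4T1 than in CD4 and 7.002 larger than in CD8. Without libraries 9 and 10 these values were 4.31 and 4.95, neither past the threshold (edgeR adjusted p = 0.441 and 0.0504). Neither passed in the fits of the 20 libraries of each pair (edgeR adjusted p = 0.413 and 0.180). Ribosomal RNA, which was left out of the comparisons in the report, held 3.05% of all counts.

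Libraries 9 and 10 stood apart from the other 28. A sample of another origin under these labels fits their Y-linked transcripts, which summed to at least 208.3 CPM against at most 1.39 CPM elsewhere. The 2 and 1 counts of Xist allow at most 0.268% of RNA from Xist-expressing cells (95% upper bound). Whether 4T1 cells themselves express Xist is not shown here, so Xist cannot bound a share of Xist-negative 4T1 cells. Wnt7b and Cited1 were at 0 CPM in libraries 9 and 10. In the other 8 4T1 libraries they were at 28.7 to 82.5 and 6.496 to 215 CPM. Gata3 was at 0.449 and 1.93 CPM against 47.8 to 211 CPM. These genes argue against a large share of 4T1 RNA. Ptn (15.72 and 10.82 CPM) and Prlr (41.98 and 43.27 CPM) were within or near the 4T1 CTRL range. Which cells express these genes was not tested, so a small share was not excluded. Large intestine markers had a median of 0 CPM in the other 13 C269 libraries. Most of these are T cell fractions, which limits this test of a C269 effect. Libraries 6 to 8, also labelled 4T1 C269, had Muc2 at 1.13, 0 and 5.39 CPM. They had Ddx3y at 0 CPM, which argues against such an effect. RNA of large intestine epithelium may be the source: 12 of 12 markers reached 10 CPM in both libraries (Lypd8 5180 and 4679 CPM, Muc2 4408 and 5348 CPM), of which 4 reached it in any other library and Car1 is also in the erythroid list, while 3 of 12 small intestine, 1 of 12 liver, 0 of 11 stomach and 1 of 12 lung markers did so. Whether the sort of 4T1 cells would remove such cells was not tested, and 4T1 CTRL held the neutrophil transcript S100a8 at 4167 CPM.

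Hormone-sensing mammary genes had higher means in the C269 libraries of each population, though none passed (adjusted p between 0.0635 and 0.0716). Not passing says little here, since the exact permutation p in CD4 was already the smallest possible (0.00794). More epithelial RNA of every kind cannot be told apart in CD4: the list rose by 1.18 more than Krt8 and Krt18 on the log2 scale (exact permutation p = 0.0317), but these stood at 86.6 and 140.5 CPM in CTRL, which would hide a small share, and Krt19 (2.26) and Cdh1 (1.33) had higher values too. Basal mammary genes argue against more mammary gland of every kind in CD4. They differed by 0.0335, 1.60 less than the hormone-sensing list (exact permutation p = 0.00794). Krt5 and Krt14 together were at 10.3 and 11.4 CPM and Ptn and Prlr at 34.0 and 245 CPM in CTRL and C269. The basal list may not be particular to mammary gland, since its mean log2(CPM + 1) was 4.09 and 4.08 in libraries 9 and 10. An unequal share of gland cell types was not excluded. A difference carried by a single library was excluded in CD4, where the rise without any 1 C269 library was 1.30 to 1.81, while in 4T1 without libraries 9 and 10 the rise of 1.78 was 1.13 without library 8 as well. An effect of C269 on luminal cells, and a difference in hormonal state between the mice, remain possible for the CD4 rise of 1.64 and were not tested.

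Cd24a was higher in the CD8 C269 libraries. RNA of B cells cannot be told apart from a change in the T cells, since 12 B cell markers other than Ms4a1 and the immunoglobulin genes together had a 1.66-fold mean (66.8 to 111 CPM; exact permutation p = 0.175) and at most 2.77-fold in a single library, against 4.38-fold for Cd24a, while Ms4a1 went from 5.40 to 35.4 CPM and Ighm from 143 to 412 CPM, and Ighg2b from 42.2 to 4.57 CPM. Without libraries 27 and 29 the epithelial and neutrophil lists had mean log2 fold changes of 0.318 and 0.357. Cd24a rose more there, at 1.74 (SE 0.27), against 2.13 (SE 0.30) with all libraries. The hormone-sensing mammary list still differed by 0.83 without these libraries (exact permutation p = 0.0357). List means do not show how much Cd24a such cells carry, so RNA of epithelial cells and of neutrophils was not excluded. The call of Cd24a ended in this subset (edgeR adjusted p = 0.0917) with 3 C269 samples left.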

How the results depend on the processing

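The alternatives without libraries 9 and 10, without libraries 27 and 29 and with the ribosomal RNA were chosen after seeing the data. DESeq2 called 1002, 16 and 15 genes in 4T1, CD4 and CD8 where edgeR called 0, 0 and 1, and 99 in 4T1 without libraries 9 and 10; the cause was not tested. Without a filter edgeR called 83 genes in CD4 and 162 in CD8, and the fit of all 30 libraries called 606 in 4T1 and 0 in CD8; the cause was not tested. RLE or library size scaling, the stricter filter, the 2-fold threshold and the ribosomal RNA kept 0, 0 and 1, and scaling moved the median log2 fold change by at most 0.0166. Without libraries 27 and 29, which leaves 3 C269 samples, CD8 had 0 genes and 2 lists. The 13, 11 and 9 lists that passed in 4T1, CD4 and CD8 became 0 in each population with an estimated correlation and 0 with fry. The difference between 4T1 and CD4 had 0 genes in the fit of 20 libraries and 0 without libraries 9 and 10, and that between 4T1 and CD8 had 0 in the fit of 20 libraries.

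Leaving out each library in turn gave 0 to 0 genes in 4T1, 0 to 10 in CD4 (10 only without library 15) and 0 to 1 in CD8 (1 only without library 25 or 26), and 13 to 15, 10 to 13 and 6 to 13 lists. The differences had 0 to 1 genes between CD4 and CD8 (1 without library 30), 0 to 16 between 4T1 and CD4 (16 without library 6, 10 without library 7) and 1 to 220 between 4T1 and CD8 (220 without library 6, 152 without library 7, 92 without library 28, 84 without library 8). No value past the threshold changed sign. Nearly all named genes were not past it: over all settings they stayed on the same side of it 1694 times, passed it 84 times, lost it 10 times and changed sign while not past it 16 times, as Cd274 in 4T1 did without libraries 9 and 10 (-0.42 to 0.28). Genes of the differences stayed on the same side 354 times, passed it 42 times and lost it 18 times, and lists that had passed kept the call 311 times and lost it 107 times. No paired analysis was possible because the columns carry no replicate letters, so the replicate block and the limma-voom fit with the animal as a random effect were not run, and the pseudocount alternative was not run because counts exist. On simulated counts of 4T1, CD4 and CD8, edgeR recovered 2.99%, 47.8% and 28.4% of 2-fold changes. DESeq2 recovered 13.4%, 65.7% and 34.3%. Among the unchanged genes edgeR made 5, 12 and 3 false calls and DESeq2 52, 30 and 31, so part of the DESeq2 calls may be false. The 4T1 counts were simulated with the spread of all 10 libraries, libraries 9 and 10 included.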

Other observations

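All tests on mammary lists, the set of 20 genes and Foxp3 in this part were chosen only after the result was seen, except the relabelled splits. Genes of hormone-sensing luminal mammary cells had higher means in C269 in each population, and none of these differences passed after adjustment. The list of 10 genes differed by 1.78 on the log2 scale in 4T1 without libraries 9 and 10 (exact permutation p = 0.0179, the smallest possible with 5 against 3), by 1.64 in CD4 (p = 0.00794) and by 1.63 in CD8 (p = 0.0159), with adjusted p of 0.0716, 0.0635 and 0.0716 over 16 tests. These values rested in part on a few libraries: the 4T1 difference was 1.13 without library 8, and the CD8 difference was 0.83 without libraries 27 and 29 (exact permutation p = 0.0357). Without Areg and Tnfsf11, which T cells also express, the CD4 difference was 1.79 (exact permutation p = 0.0159). Milk and alveolar genes differed by -0.37, -0.46 and -0.20 in the same libraries (exact permutation p = 0.268, 0.246 and 0.540). Basal mammary genes differed by 0.15 in 4T1 without libraries 9 and 10 and by -0.14 in CD8 (exact permutation p = 0.446 and 0.587), and Krt8 with Krt18 by 0.81, 0.46 and 1.02 in the 3 populations (exact permutation p = 0.214, 0.0556 and 0.175).

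The 20 genes with the smallest p among those higher in 4T1 C269 without libraries 9 and 10 also had higher means in C269 in the T cell fractions, with the exceptions given. In CD4, 18 of the 20 had a higher mean in C269 and the set differed by 1.59 (exact permutation p = 0.0159), and in CD8 all 20 had and the set differed by 1.56 (exact permutation p = 0.0238). The CD8 difference was 0.73 without libraries 27 and 29 (exact permutation p = 0.0536), and its p was 0.0635, 0.0714 and 0.0635 without CTRL library 21, 22 or 24. Of the 20, 3 are in the hormone-sensing list and 3 in the epithelial list. The populations may come from the same mice, so these values, 0.0159 and 0.0238, are not independent of each other or of the 4T1 libraries.

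Il1rl1, Gata3, Il2ra and Areg, which tissue regulatory T cells and Th2 cells express, differed together by 1.02 on the log2 scale in CD4. Areg is also in the hormone-sensing mammary list, which differed by 1.64 in these libraries, and Gata3 is also a luminal gene (211 CPM in 4T1 library 8), so part of their values may be RNA of luminal cells. Areg, an epidermal growth factor receptor ligand, averaged 102 ± 37.4 CPM in CTRL and 199 ± 52.5 CPM in C269, with 5 of 5 C269 libraries above every CTRL library. A larger share of Foxp3-expressing cells cannot be told apart from a change within cells: the 4 genes differed by 0.686 more than Foxp3 (95.2 ± 18.4 to 120.1 ± 26.3 CPM), but they were chosen for their rise, all within the 30 smallest p in CD4.

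Each comparison was also run on 100 splits of its libraries, the real one included, and the number of these with at least as many calls as the real one, itself included, is given. For genes the number was 2 in CD8 (real 1, highest other 1), under the limit set beforehand. Chance was not excluded even so, since this number rests on 1 gene whose call held in 2 of 10 fits leaving out 1 library. In 4T1 (real 0, highest other 469), CD4 (real 0, highest other 20) and the difference between CD4 and CD8 (real 0, highest other 1) it was 100 by construction, since no split can have fewer than 0 calls, and this says nothing about chance. For lists it was 49 in 4T1 (real 13, highest other 26), 27 in CD4 (real 11, highest other 14) and 38 in CD8 (real 9, highest other 23), so chance was not excluded for any list count. With treatment relabelled within each population it was 11 between 4T1 and CD4 (real 1, highest other 699) and 23 between 4T1 and CD8 (real 1, highest other 1154), and chance was not excluded for these. Splits that call 469 to 1154 genes point to structure among the samples, and its source was not tested.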
